A study of Bos taurus with 12 samples.

How the data were processed

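The series holds RNA sequencing of cattle (Bos taurus) precursor adipocytes, 12 libraries in 4 groups of 3, collected 48 h after transfection. Per the labels, RNA was extracted with TRIzol and made into stranded libraries from polyadenylated RNA. Groups were taken from the sample titles, and all 12 columns of each table matched a title, so 0 columns with values per sample were left unmapped. The labels do not say that replicates were separate cultures, so every p-value measures the spread between these libraries only, which may be technical. The authors deposited raw read counts per gene, and the submitters' processing notes name fastp 0.23.0 and featureCounts of Subread 1.5.1; the aligner, the genome build, the counting strand and the treatment of reads that map to several genes are not given in the sources used here. The authors also deposited RPKM, which equalled the counts divided by exon length and column total to a relative difference of at most 6.6e-14. Between 66.2 and 69.3 percent of nonzero counts were even, as when both reads of a pair are counted; halved counts were therefore tried. The raw reads were not analysed here.

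The count table names 29240 genes, of which 11536 (39.5 percent) carry a LOC number. A further 2 entries that name no gene held 0.087 to 0.116 percent of counts and were left out. Of the gene identifiers, 24954 (85.3 percent) were found as symbols in a reference gene table, where 25.3 percent of the matched genes had the same start and end, so coordinates are given as the count table has them. Counts assigned to genes summed to 36.1, 42.7 and 35.9 M in si, 32.2, 28.9 and 31.1 M in si_NC, 36.4, 35.8 and 32.7 M in OE, and 36.0, 38.2 and 35.1 M in OE_NC. Replicates correlated at 0.9839 to 0.9927 (Pearson, log2 CPM). The first 2 principal components held 25.9 and 19.0 percent of the variance.

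Differences were tested with edgeR 4.0.16 in R 4.3.3: TMM scaling, genes kept by filterByExpr (minimum count 10, minimum total 15; 16300 genes), and the quasi-likelihood F test in a single fit of all 12 libraries with a mean per group, which leaves 8 residual degrees of freedom. P-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. The contrasts were si minus si_NC, OE minus OE_NC, the difference of these 2 changes, and OE_NC minus si_NC. Standard errors are the log2 change divided by the root of the F statistic. HGFAC was also tested by exact permutation of CPM, 3 against 3, where the smallest p is 0.1. The overlap of the experiments was set against the number expected for independent lists.

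The 28 gene lists, the contrasts, the tests and the rule for naming genes were set before the data were examined. Of 686 listed symbols 3 were matched by a synonym (GRO1 for CXCL1, CYR61 for CCN1, CTGF for CCN2) and 23 were not matched. Lists with at least 3 tested genes were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over the lists, and beside it with an estimated correlation and with fry. Genes named were HGFAC; the 10 largest rises and 10 largest falls among called genes with a symbol, a mean of at least 5 CPM and no overlap between the 2 groups (5 each for the controls), a separation that chance gives for 10 percent of genes; up to 4 called members per list, or its most abundant members; up to 5 genes per direction in the overlap; and the 10 smallest p-values of the difference. Some list members that this rule selects are not named. Exon overlaps of named genes were read from the coordinates of the count table.

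The procedure was tested on simulated data. Of genes changed 1.5-fold, 2-fold and 4-fold, edgeR recovered 45.6, 79.4 and 95.7 percent for interference (16001 genes; 8 unchanged genes among 155 calls), 53.6, 74.1 and 90.4 percent for overexpression (16006 genes; 12 among 155), 15.6, 67.2 and 83.8 percent for the difference (15996 genes; 10 among 122) and 41.3, 69.4 and 89.1 percent for the controls (16009 genes; 2 among 135). Camera found a list raised 1.3-fold and 0 others, in counts drawn independently for each gene. The real lists had estimated correlations of up to 0.905. The simulation therefore does not bear on false list calls at the preset correlation. The gene counts were drawn the same way, with no structure shared between genes of a library. Their shares of recovered and false calls may therefore not carry over to the real libraries.

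Alternatives were size factors of DESeq2, library totals, the Wald test of DESeq2 1.42.0, no filter on low counts, a filter of 5 CPM in 3 libraries, a fit of only the groups compared, replicate number as a block, limma on log2 RPKM with 1 or 0.1 added, a change of at least 2-fold, and leaving out each library. Chosen after seeing the data were the fit without si replicate 3 and si_NC replicate 2 together, an offset for the trend of each library on gene length (natural spline, 4 degrees of freedom) and halved counts. GC content could not be examined, since no genome sequence was at hand.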

Results

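Precursor adipocytes of cattle were profiled 48 h after transfection in 4 groups of 3 libraries. The si group stood against its negative control si_NC, and the OE group, which received a pcDNA3.1 plasmid carrying HGFAC, stood against the pcDNA3.1 negative control OE_NC. HGFAC encodes the HGF activator, a secreted serine protease that cleaves the precursor of hepatocyte growth factor. The labels name no target for si. The cells carried abundant stromal and contractile transcripts, with mean levels over the 12 libraries of 15700 CPM for CALD1, 7210 CPM for COL1A2 and 5950 CPM for VIM, and the proliferation gene MKI67 averaged 1330 CPM. Genes of mature fat cells were low: the median listed adipocyte and lipid droplet gene averaged 1.44 CPM. The highest markers of other cell types were SPP1 for bone and cartilage (116 CPM), FLT1 for endothelium (64.2 CPM) and ACTA1 for muscle (12 CPM). Those for immune cells and epithelium were CD68 (4.4 CPM) and KRT19 (1.91 CPM). Levels below are normalised CPM (mean ± SD of 3 libraries), changes are log2 fold changes ± SE, and p-values from edgeR are Benjamini-Hochberg adjusted over the 16300 genes tested.

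HGFAC mRNA rose in OE from 0.393 ± 0.127 to 161.0 ± 26.3 CPM, a log2 change of 8.67 ± 0.19 or 407-fold (95% interval 306-fold to 542-fold; edgeR adjusted p = 4.31e-13; 3 against 3 libraries). The exact permutation p of the CPM was 0.1, the smallest that 3 against 3 libraries can give. In si, HGFAC stood at 0.658 ± 0.165 CPM against 0.83 ± 0.099 CPM in si_NC (log2 change −0.35 ± 0.27, 95% interval −0.92 to 0.22, edgeR adjusted p = 0.512, exact permutation p = 0.3). These values rest on 22 to 31 reads per si library and 21 to 28 per si_NC library, and changes within the interval stay open. The log2 change was −0.57 without si replicate 1 and −0.20 without si replicate 2. HGFAC was lower in OE_NC than in si_NC (log2 −1.08 ± 0.30, edgeR adjusted p = 0.02). Its exons, on the minus strand of chromosome 6 (115437167 to 115445298 in the coordinates of the count table), sum to 2895 bases. The counts do not separate transcripts of the plasmid from those of the genome.

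**Figure D1:**
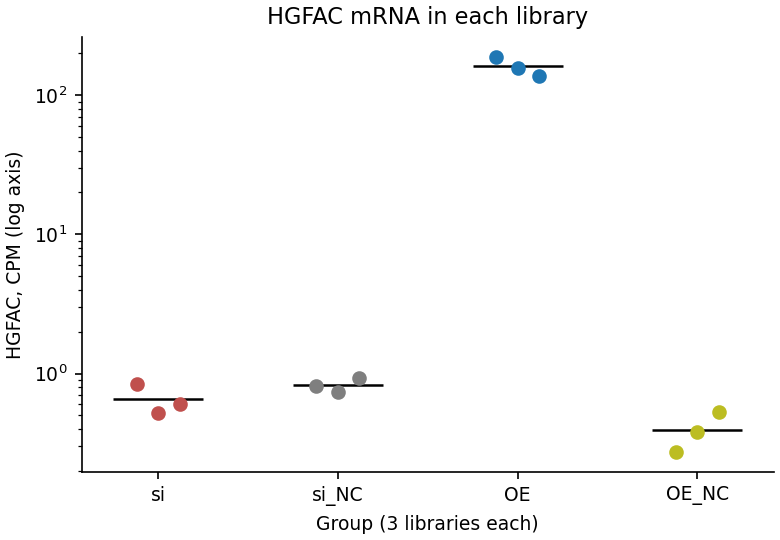
HGFAC level in each library, in normalised CPM on a log axis, for si, si_NC, OE and OE_NC (3 libraries each, bars at the means). The means were 0.658, 0.83, 161.0 and 0.393 CPM.

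In si, CDH2, which encodes N-cadherin, rose from 38.5 ± 4.71 to 71.5 ± 1.82 CPM (log2 0.90 ± 0.09, edgeR adjusted p = 0.000506). SPAG9, a scaffold of JNK signalling, rose from 107 ± 11.6 to 188 ± 16.2 CPM (log2 0.81 ± 0.09, edgeR adjusted p = 0.000776). CCNG1, the p53 target cyclin G1, fell from 208 ± 6.2 to 125 ± 3.2 CPM (log2 −0.74 ± 0.06, edgeR adjusted p = 9.46e-05). FEM1A, a substrate receptor of a ubiquitin ligase, fell from 90.2 ± 10.6 to 30.4 ± 4.03 CPM (log2 −1.57 ± 0.21, edgeR adjusted p = 0.00309). In all, 414 genes changed, 150 upward and 264 downward, with a median absolute log2 change of 0.44, and 29 of them changed at least 2-fold (21 upward, 8 downward). Further large rises were those of SYT11 (11.2 to 19.7 CPM), the chemokine receptor ACKR3 (13.5 to 23.7 CPM), PTGIS (prostacyclin synthase, log2 0.73), GLB1 (log2 0.69), SHISA4 (log2 0.68), the stromal marker THY1 (9.22 to 14.6 CPM) and CRIP1 (log2 0.65). BANK1 fell from 30.8 ± 12.9 to 9.39 ± 2.81 CPM (log2 −1.71 ± 0.29, edgeR adjusted p = 0.00973); its call ended without si_NC replicate 1 (log2 −1.40). EREG, a ligand of the EGF receptor, fell from 17.1 ± 2.94 to 8.79 ± 1.45 CPM (log2 −0.96 ± 0.15, edgeR adjusted p = 0.00786). PES1, a ribosome assembly factor, fell from 402 ± 66.6 to 239 ± 7.66 CPM. Other large falls were those of FAM241A (log2 −1.16), GFER (log2 −0.87), NOL7 (log2 −0.82), IL7R (log2 −0.77) and PARVB (log2 −0.76). In each gene of this paragraph, all 3 libraries of the higher group lay above all 3 of the lower. The rule for naming the largest rises and falls required this, so it adds no support. Exon overlaps leave 2 calls uncertain, since the strand used in counting is not stated. TRDMT1 (log2 0.65 ± 0.08) shares 71 exon bases with the far more abundant VIM on the other strand. FGF2 (log2 −0.78 ± 0.13) shares 1122 of 6594 with NUDT6. Without any single library, CDH2, SPAG9, CCNG1, FEM1A, SYT11, ACKR3, EREG, PES1, FGF2 and TRDMT1 stayed called, and the other genes of this paragraph lost their call in 1 to 5 of 6 refits, with the sign kept (PARVB −0.47 without si_NC replicate 1). The count of changed genes was 56 without si_NC replicate 1, 69 without si replicate 2, 73 without si replicate 1, 135 without si_NC replicate 3, but 685 without si replicate 3 and 1083 without si_NC replicate 2. Scaling by library totals gave 298 upward of 404 genes, DESeq2 called 1125, and edgeR on these 6 libraries alone called 8.

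Among the fixed gene lists, 8 of the 13 mitochondrially encoded genes rose with si (11 adjusted over the list alone) and none fell. The list median was a log2 change of 0.31 (limma camera adjusted p = 1.19e-08; adjusted p = 0.456 with an estimated correlation). ATP8, a subunit of ATP synthase, rose from 1916 ± 75.5 to 2756 ± 23.3 CPM (log2 0.52 ± 0.06, edgeR adjusted p = 0.00171), with ND6 (log2 0.51), CYTB (log2 0.36) and COX3 (log2 0.33). ATP8 shares 40 of its 201 exon bases with ATP6, and ND6 shares 17 with ND5. Mitochondrial mRNA made up 2.01, 2.03 and 2.26 percent of counts in si and 1.58, 1.7 and 1.63 percent in si_NC. The 20 genes of cholesterol synthesis and uptake fell as a list (median log2 −0.30; limma camera adjusted p = 2.38e-05; adjusted p = 0.767 with an estimated correlation). It had 1 called member, or 4 adjusted over the list alone: SC5D, sterol C5-desaturase, at 54.5 ± 5.07 against 72.2 ± 5.93 CPM (log2 −0.41 ± 0.10). The 30 collagens and matrix proteins had a median log2 change of 0.20, with 28 positive (limma camera adjusted p = 0.000368; adjusted p = 0.767 with an estimated correlation). Of these 1 was called, also adjusted over the list alone: biglycan, BGN, at 37.4 ± 2.91 against 26.9 ± 2.83 CPM. Of 21 TGF-beta and YAP targets, 3 rose (4 adjusted over the list alone): TGFB2 (14.2 to 22.1 CPM), ID2 (log2 0.57) and TGFBI (log2 0.50). Their list median was 0.16 (limma camera adjusted p = 0.0217; adjusted p = 0.456 with an estimated correlation). Of 23 p53 targets, 4 fell, also adjusted over the list alone: CCNG1, ZMAT3 (log2 −0.64 ± 0.07), the repair polymerase POLK (log2 −0.44) and the damage sensor XPC (log2 −0.38). The p53 list passed limma camera at an adjusted p of 0.0214 (adjusted p = 0.749 with an estimated correlation), with a median log2 change of −0.077 that became 0.004 with library totals. The 4 epithelial markers tested had a median log2 change of 0.99 (limma camera adjusted p = 0.0108; adjusted p = 0.346 with an estimated correlation). EdgeR called 0, or 1 adjusted over the list alone, with 3 at an unadjusted p under 0.05. DESeq2 and limma called 0. Epithelial levels were low, with KRT19 the highest (log2 0.65, edgeR adjusted p = 0.232) and GRHL2 next in level (log2 0.98, edgeR adjusted p = 0.0994). GRHL2 shares 1671 of its 11327 exon bases with the more abundant NCALD on the other strand, so its value is uncertain. Of the members named here, ATP8, CCNG1, ZMAT3 and XPC stayed called without any single library; the others lost their call in 1 to 5 of 6 refits. List calls ended without si replicate 3 for collagens (median 0.12), p53 targets (−0.056), TGF-beta and YAP targets (0.093) and epithelial markers (0.94). They also ended without si_NC replicate 1 for collagens (0.11) and TGF-beta and YAP targets (0.10), and without si_NC replicate 2 for p53 targets (−0.13) and TGF-beta and YAP targets (0.18). Calls that held moved to a median of −0.51 for cholesterol without si replicate 3, 0.32 for collagens without si_NC replicate 2, and −0.17 and −0.18 for p53 targets without si replicates 1 and 2.

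The other 22 lists did not pass limma camera in si with all libraries. In refits without 1 library, fatty acid synthesis passed without si replicate 3 (median log2 −0.24) or si_NC replicate 3 (−0.17), and DNA replication without si replicate 2 (−0.11) or si_NC replicate 2 (−0.23). G2/M genes passed without si replicate 3 (0.13), si_NC replicate 1 (0.17) or si_NC replicate 3 (0.092), ribosomal proteins without si replicate 1 (−0.13), si replicate 2 (−0.10) or si_NC replicate 2 (−0.13), and interferon genes without si_NC replicate 2 (0.23). Single members were called in several, each lost in 3 to 5 of 6 refits without 1 library. PLAU, the urokinase that can also cleave pro-HGF, rose among 13 genes of HGF activation and signalling (45.2 ± 4.46 to 62.9 ± 12.4 CPM; log2 0.48, and 0.30 without si replicate 3). The retinoid receptor RXRA fell among 21 adipogenic transcription factors (log2 −0.65), and SOX9 rose among 19 anti-adipogenic regulators (3.51 to 5.28 CPM). FABP5, a fatty acid binding protein, fell among 21 adipocyte and lipid droplet genes (196 ± 16.3 to 158 ± 10.4 CPM). THY1 rose and ALCAM fell (log2 −0.44) among 17 preadipocyte and stromal markers, TIMP1 rose among 17 matrix proteases and inhibitors (log2 0.40), and CSPG4 rose among 12 smooth muscle and pericyte markers (log2 0.50). TRIM25 fell among 44 interferon response genes (log2 −0.33), TNFAIP6 rose among 24 inflammatory genes (log2 0.48), and CCNE1, cyclin E1, fell among 29 DNA replication genes (log2 −0.99). Among 17 cytosolic heat shock genes HSP90AA1 rose (log2 0.36) while its paralog HSP90AB1 (log2 −0.36), HSPA1A (log2 −0.34) and DNAJA1 (log2 −0.31) fell. EGR3 (log2 0.83) and DUSP1 (log2 0.41) rose among 25 immediate early genes, and VEGFA (118 to 152 CPM) and NDRG1 (log2 0.36) among 24 glycolysis and hypoxia genes. In the remaining lists edgeR called 0 members. Counts at an unadjusted p under 0.05 and by DESeq2 were 4 and 3 of 21 for fatty acid synthesis, 4 and 1 of 27 for fatty acid oxidation, and 4 and 1 of 30 for G2/M genes. They were 11 and 8 of 28 for the unfolded protein and integrated stress response, and 4 and 0 of 38 for ribosomal proteins. For markers of other cells they were 3 and 1 of 6 for muscle, 0 and 0 of 8 for endothelium, 1 and 1 of 9 for immune cells, and 3 and 1 of 9 for bone. Limma on RPKM called 1 fatty acid synthesis gene, 1 of the stress response and 1 immune marker among these, and 0 in the others. FASN, the fatty acid synthase, stood at 107 ± 22.6 against 118 ± 15.3 CPM (edgeR adjusted p = 0.632) and MKI67 at 1378 ± 86.5 against 1299 ± 228 CPM (edgeR adjusted p = 0.704). Median and mean differed in sign for HGF signalling (−0.019 and 0.16), adipogenic factors (0.005 and −0.015), inflammatory genes (−0.053 and 0.027) and glycolysis (−0.041 and 0.067).

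With HGFAC overexpression, 13 of 44 listed interferon response genes and 4 of 24 inflammatory genes rose. IRF1, a transcription factor of the interferon response, rose from 13.0 ± 0.823 to 26.9 ± 1.96 CPM (log2 1.05 ± 0.12, edgeR adjusted p = 0.00081). BIRC3, an NF-kB target, rose from 23.9 ± 0.902 to 39.6 ± 1.56 CPM (log2 0.73 ± 0.08, edgeR adjusted p = 0.000418). The chemokine gene CXCL2 rose from 7.19 ± 0.383 to 16.4 ± 1.92 CPM (log2 1.19 ± 0.19, edgeR adjusted p = 0.00728). PTX3, a secreted pattern recognition protein, from 11.9 ± 3.94 to 31.9 ± 2.11 CPM (log2 1.42 ± 0.26, edgeR adjusted p = 0.0144). Downward, profilin 1 (PFN1) fell from 340 ± 47.8 to 182 ± 25 CPM (log2 −0.90 ± 0.12, edgeR adjusted p = 0.00243). ID1, an inhibitor of bHLH factors, fell from 7.92 ± 0.569 to 4.003 ± 0.711 CPM (log2 −0.98 ± 0.13, edgeR adjusted p = 0.00272). In all, 728 genes changed, 362 upward and 366 downward, with a median absolute log2 change of 0.48, and 86 changed at least 2-fold (16 upward, 70 downward). Other large rises were those of the cytochrome CYP3A4 (6.65 to 17.0 CPM), MEOX1 (log2 1.17), MYL4 (log2 1.14), MYH11 (log2 1.01), the complement protease C1R (log2 1.00) and the guanylate-binding protein GBP4 (4.79 to 8.996 CPM). CYP3A4, CXCL2 and GBP4 have close paralogs with which reads can be shared. Further falls were those of RN7SL1 (log2 −1.24), SERP1 (16.9 to 8.17 CPM), KLC2 (log2 −0.95), the respiratory subunit COX5A (12.7 to 6.72 CPM), IER5L (log2 −0.90), CATSPER2 (log2 −0.86), PYCR3 (log2 −0.85) and PPP1R16A (log2 −0.85). In each gene named so far in this paragraph, all 3 libraries of the higher group lay above all 3 of the lower, as the naming rule required of the largest rises and falls. Exon overlaps leave MYH11 (686 of 6667 bases shared with NDE1) and CATSPER2 (176 with PDIA3), whose partners are more abundant, uncertain. The count of changed genes was 225 without OE replicate 1, 19 without OE replicate 2, 35 without OE replicate 3, 45 without OE_NC replicate 1 and 32 without OE_NC replicate 2. IRF1, BIRC3, PFN1, ID1, CYP3A4, COX5A and IER5L stayed called in every such refit, while CXCL2 lost its call without OE_NC replicate 2 (log2 1.19) and the other genes of this paragraph in 3 to 5 of 6 (PPP1R16A reached −1.31 without OE replicate 1). Scaling by library totals gave 159 upward of 812 genes, DESeq2 called 1546, and edgeR on these 6 libraries alone called 1621.

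Among the fixed lists, 13 of 44 interferon response genes rose with overexpression and none fell, or 20 and 3 adjusted over the list alone. Their median log2 change was 0.37, with 35 positive (limma camera adjusted p = 1.55e-06; adjusted p = 0.789 with an estimated correlation). Beside IRF1 and GBP4, they included the nucleic acid sensor ZBP1 (0.374 ± 0.142 to 1.35 ± 0.187 CPM, log2 1.84) and GBP5 (0.607 ± 0.0544 to 1.73 ± 0.444 CPM, log2 1.51). The calls of GBP4, GBP5 and ZBP1 ended without OE replicate 2 (log2 0.93, 1.41 and 1.92), OE replicate 3 (0.87, 1.38 and 1.74), OE_NC replicate 1 (0.72, 1.49 and 1.56) or OE_NC replicate 2 (0.99, 1.44 and 1.89). That of ZBP1 also ended without OE replicate 1 (1.83). Of 24 inflammatory and NF-kB genes, 4 rose (8 adjusted over the list alone): CXCL2, BIRC3, GRO1 (17.4 to 30.8 CPM) and NFKBIZ (log2 0.52). This list had a median of 0.25 (limma camera adjusted p = 0.012; adjusted p = 0.456 with an estimated correlation), and its call ended without OE replicate 1 (median 0.11). Immune cell markers did not rise with them: CD68 stood at 3.81 ± 0.726 in OE and 4.43 ± 0.0706 CPM in OE_NC, and CD163 had a log2 change of −0.13. The 9 markers had a median of −0.20, with 0 called by edgeR, DESeq2 or limma and 1 lower at an unadjusted p under 0.05. Of 30 collagens and matrix proteins, 2 rose (8 adjusted over the list alone): fibronectin, FN1 (531 ± 89.2 to 802 ± 9.87 CPM), and periostin, POSTN (802 ± 6.51 to 999 ± 7.97 CPM). The matrix list had a median of 0.25 (limma camera adjusted p = 0.000249; adjusted p = 0.84 with an estimated correlation), which became 0.12 without OE_NC replicate 1 and 0.15 with the trend on exon length removed. Of 29 DNA replication genes edgeR called 0, with 9 lower at an unadjusted p under 0.05, 3 lower by DESeq2 and 1 by limma on RPKM. Their median log2 change was −0.25, with 1 positive (limma camera adjusted p = 0.000248; adjusted p = 0.84 with an estimated correlation); MCM10 stood at −0.10 and RRM1 at −0.035. Without OE_NC replicate 1 that median was −0.14. Of 25 immediate early genes, 4 fell (6 adjusted over the list alone): FOSB (log2 −1.50), DUSP5 (log2 −1.02), PHLDA1 (log2 −0.37) and DUSP1 (log2 −0.32). The median there was −0.16 (limma camera adjusted p = 0.012; adjusted p = 0.84 with an estimated correlation). Without 1 library, the calls of GRO1, NFKBIZ, POSTN and DUSP1 ended in 6 of 6 refits and those of FN1, FOSB, DUSP5 and PHLDA1 in 5. Limma fry, which tests for a shift one way, did not pass the interferon list (adjusted p = 0.058).

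**Figure D2:**
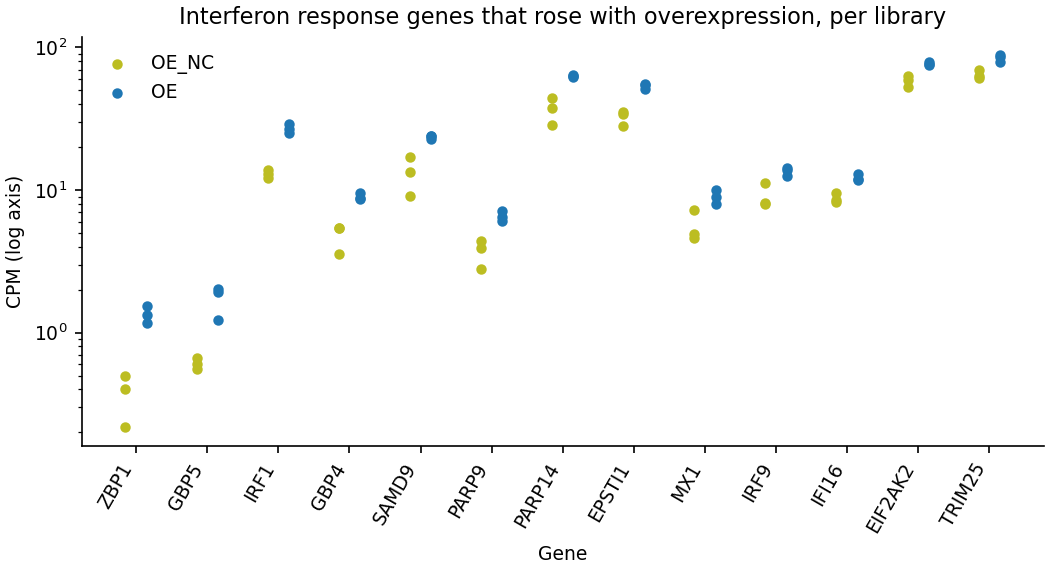
Level of the 13 interferon response genes that rose with overexpression, in normalised CPM on a log axis, in the 3 OE_NC and 3 OE libraries. The median log2 change of all 44 tested list members was 0.37.

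Short and mitochondrial transcripts were lower in OE. Of the 13 mitochondrially encoded genes, 9 fell, or 11 adjusted over the list alone (median log2 −0.37; limma camera adjusted p = 4.2e-10; adjusted p = 0.456 with an estimated correlation). ATP8 stood at 1524 ± 69.6 against 2544 ± 155 CPM (log2 −0.74 ± 0.07, edgeR adjusted p = 7.34e-05), beside ND6 (log2 −0.49), ND1 (log2 −0.46) and ND2 (log2 −0.44). Of 38 cytosolic ribosomal protein genes, 9 fell, or 18 adjusted over the list alone (median log2 −0.28; limma camera adjusted p = 4.2e-10; adjusted p = 0.84 with an estimated correlation). RPL6 stood at 1307 ± 104 against 2064 ± 237 CPM (log2 −0.66 ± 0.12), beside RPL38 (log2 −0.73) and RPL30 (log2 −0.57). Without OE_NC replicate 1 the ribosomal median was −0.18. ATP8 stayed called without any single library, and the other genes named here lost their call in 2 to 5 of 6 refits. These genes are short, with median exon lengths of 781 bases for the mitochondrial and 715 for the ribosomal list, against 3205 for the interferon list. Across genes, which are not independent replicates, the log2 change with overexpression rose with exon length (Spearman 0.35), where the value was −0.018 for interference. In the decile of the shortest genes (54 to 896 bases, 1630 genes) 143 fell and 5 rose (median log2 −0.30), and in that of the longest (7281 to 106333 bases) 5 fell and 100 rose (median log2 0.14). Within the control group, OE_NC replicate 1 lay furthest along this trend. The Spearman correlation of its relative log2 level with length was −0.42, against −0.19 and −0.10 in OE_NC replicates 2 and 3 and 0.15, 0.14 and 0.085 in OE. With the trend on length removed from each library, overexpression changed 431 genes, with 4 of the ribosomal list (median log2 −0.058) and 1 of the mitochondrial list (median −0.13) falling. In that refit 10 of the interferon list rose (median 0.38).

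The other 21 lists did not pass limma camera with overexpression and all libraries. Glycolysis and hypoxia genes passed without OE replicate 2 (median log2 −0.18), OE replicate 3 (−0.20) or OE_NC replicate 2 (−0.18) and with library totals (−0.23), and fatty acid synthesis without OE_NC replicate 3 (0.17). HGFAC and PLAU (47.2 ± 2.97 to 64.1 ± 3.57 CPM) rose among 13 genes of HGF activation and signalling, and GATA2 fell among 19 anti-adipogenic regulators (26.3 ± 3.28 to 17.9 ± 1.44 CPM). INHBA, a subunit of activin A, rose from 126 ± 8.11 to 187 ± 1.95 CPM (log2 0.57 ± 0.07, edgeR adjusted p = 0.00192) among 21 TGF-beta and YAP targets, where ID1, AJUBA (log2 −0.50), ID2 (log2 −0.43) and ID3 (log2 −0.39) fell; ID3 was named after its value was seen. Of 12 smooth muscle and pericyte markers 3 rose: MYH11, CALD1 (13690 ± 1130 to 18510 ± 454 CPM) and DES (log2 0.42); among 6 muscle markers ACTA1 fell (log2 −0.68). MMP14 rose among 17 matrix proteases and inhibitors (log2 0.41), CDC20 fell among 30 G2/M genes (log2 −0.54). RRM2B rose (log2 0.66) while BAX fell (58.9 ± 4.55 to 38.8 ± 4.42 CPM) among 23 p53 targets. MANF fell among 28 genes of the unfolded protein and integrated stress response (log2 −0.53). HSPB1 (log2 −0.40) and DNAJB1 (log2 −0.33) fell and DNAJB4 rose (log2 0.27) among 17 heat shock genes, and GAPDH fell among 24 glycolysis and hypoxia genes (log2 −0.32). Among these members HGFAC, INHBA and ID1 stayed called without any single library. PLAU and DNAJB4 lost their call in 6 of 6 refits, and the others, apart from ID3, whose refits were not kept, in 2 to 5. In the lists on fat cell identity and lipid metabolism edgeR called 0 genes. Counts at an unadjusted p under 0.05 and by DESeq2 were 7 and 1 of 21 adipogenic transcription factors, 4 and 1 of 21 adipocyte and lipid droplet genes, and 4 and 1 of 21 for fatty acid synthesis. They were 1 and 0 of 20 for cholesterol, 4 and 0 of 27 for fatty acid oxidation, and 8 and 3 of 17 stromal markers. Limma on RPKM called 2 adipogenic transcription factors and 1 stromal marker among these. The endothelial, epithelial and bone markers held 0 calls by edgeR, with 0, 0 and 1 at an unadjusted p under 0.05 and 0, 0 and 1 by DESeq2, and 0 by limma. Values of abundant members were FABP5 at a log2 change of 0.22 (edgeR adjusted p = 0.0992), PLIN2 at 0.16, ACSL4 at 0.15, HADHA at 0.05 and VIM at −0.14. Median and mean differed in sign for TGF-beta and YAP targets (0.042 and −0.052), the stress response (0.017 and −0.015) and epithelial markers (−0.029 and 0.028).

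**Figure D3:**
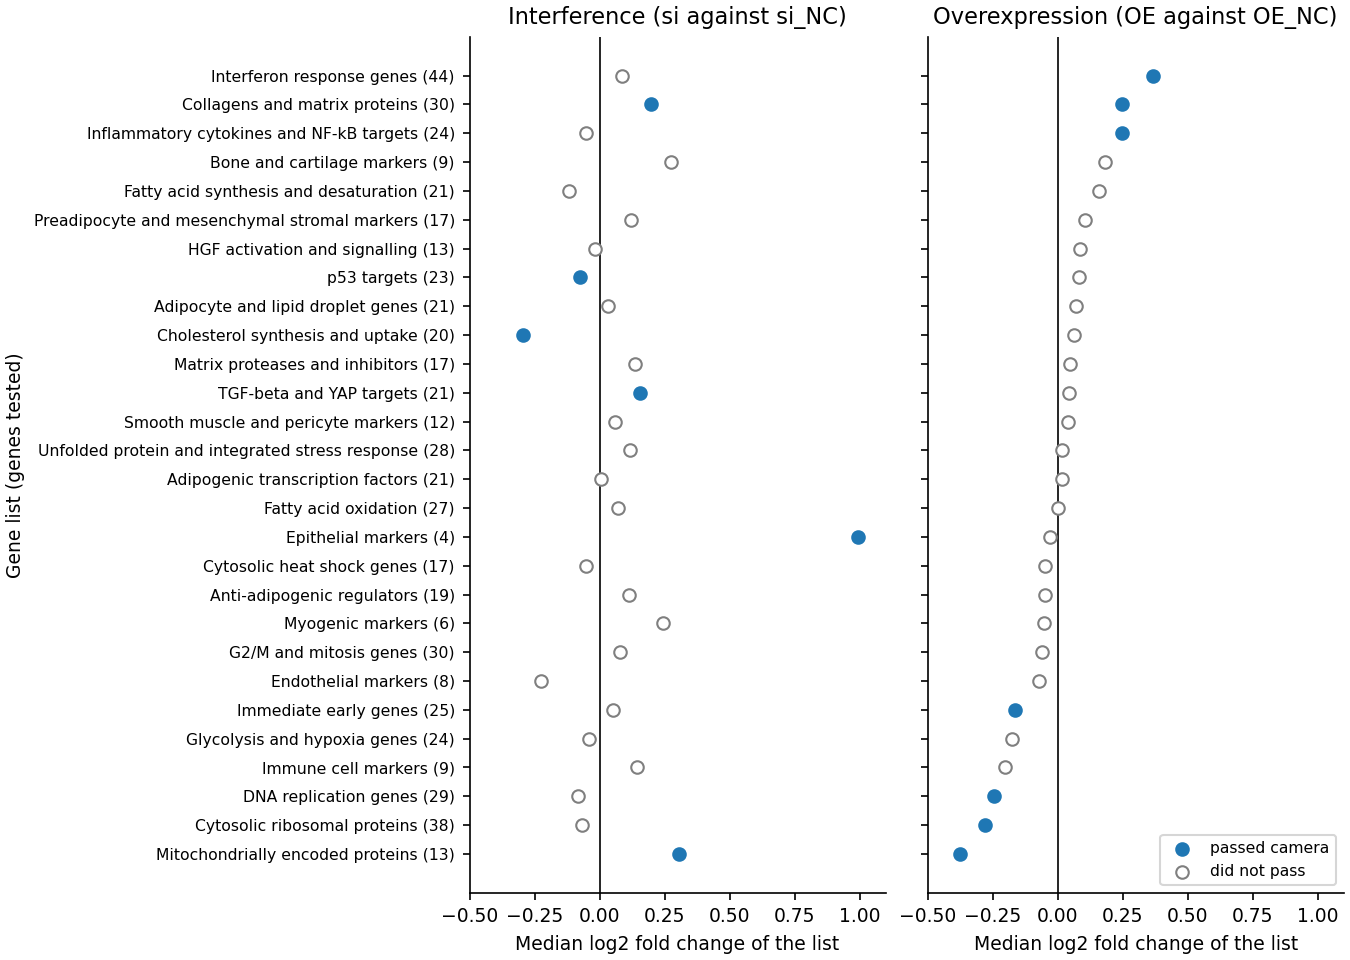
Median log2 fold change of the genes of each fixed list (number tested in brackets) in si against si_NC and OE against OE_NC, with filled points for lists past limma camera at a preset correlation. With overexpression the medians ran from −0.37 (mitochondrially encoded genes) to 0.37 (interferon response genes); the p53 point for interference, −0.077, turned to 0.004 with library totals.

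The response differed between the experiments for 1371 genes, 700 with the higher log2 change in overexpression and 671 with the lower. Apart from HGFAC (difference 9.02 ± 0.39, edgeR adjusted p = 6.39e-09), the smallest p-values belonged to ATP8 (difference −1.26 ± 0.09, edgeR adjusted p = 5.4e-06) and NEXN, an actin-binding protein. NEXN fell with si from 11890 ± 569 to 7542 ± 391 CPM and rose with overexpression from 7230 ± 87.5 to 9204 ± 475 CPM (difference 1.01 ± 0.09, edgeR adjusted p = 7.18e-05). CCNG1 (difference 0.88 ± 0.09), TRDMT1 (−1.09 ± 0.12), CDH2 (−1.11 ± 0.13), ND6 (−1.003), PFN1 (−1.29 ± 0.16), CDADC1 (0.69, with 2273 of 4544 exon bases shared with LOC104970162) and COX3 (−0.76) followed. These had edgeR adjusted p-values of 0.000212 to 0.00107. Without single libraries the count was 603 (si replicate 1), 616 (si replicate 2), 2152 (si replicate 3), 900 (si_NC replicate 1), 735 (OE replicate 1), 598 (OE replicate 2), 826 (OE replicate 3) and 588 (OE_NC replicate 2). Scaling by library totals gave 265 upward of 1534 genes.

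Of the genes called in either experiment, 70 were called in both, and 67 of these went in opposite directions, where 9.2 would be expected for independent lists. The 35 that fell with si and rose with overexpression included the cholesterol exporter ABCA1 (log2 −0.48 and 0.45), BABAM1 (−0.49 and 0.39), the kinase RIPK1 (−0.36 and 0.41), NEXN and LOC100848689 (−0.46 and 0.42). Of the 32 that rose with si and fell with overexpression, 8 were mitochondrially encoded and 15 carried only a LOC number or locus tag, among them LOC104971817 (log2 1.82 and −2.38), LOC783033 (0.91 and −1.02), LOC781197 (0.88 and −1.18), LOC616200 (1.202 and −0.86) and LOC784052 (0.85 and −0.95). The same direction was seen for 3, against 9.3 expected (32 without si_NC replicate 2 and 116 without the filter on low counts): PLAU (0.48 and 0.44), TRIP11 (0.39 and 0.34) and S100A5 (−0.48 and −0.44). Across genes, which are not independent replicates, the log2 changes of the 2 experiments had a Pearson correlation of −0.16 and a Spearman correlation of −0.13. The opposite count was 11 without si replicate 1, 12 without si replicate 2, 237 without si replicate 3, 12 without si_NC replicate 1, 12 without si_NC replicate 3, 18 without OE replicate 1, 2 without OE replicate 2, 6 without OE replicate 3, 15 without OE_NC replicate 1 and 5 without OE_NC replicate 2. The numbers expected in these refits were 0.1 to 1.7, but 28.6 without si replicate 3. Without si_NC replicate 2 the opposite count was 93, with 34.9 expected and a Pearson correlation of −0.061. Without OE_NC replicate 3 it was 46, with 7.4 expected. DESeq2 gave 232, with 53.5 expected.

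**Figure D4:**
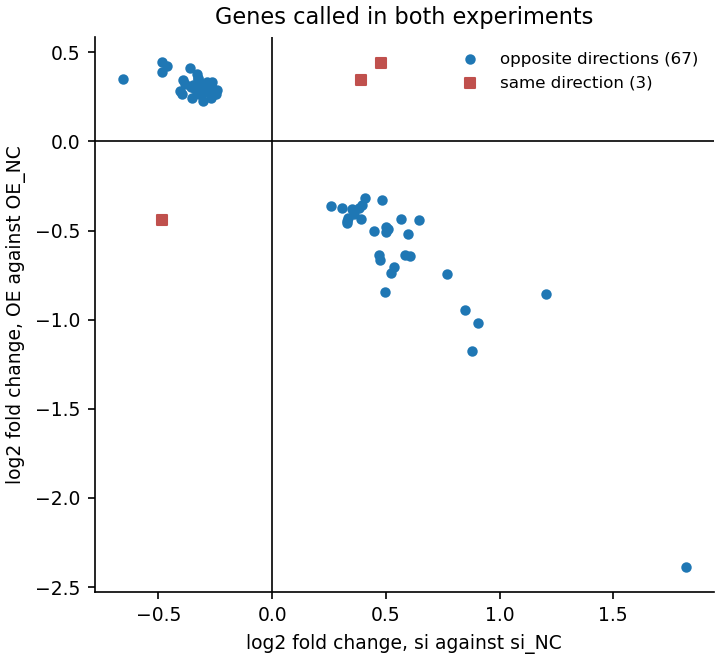
Genes called in both experiments, with the log2 fold change of si against si_NC on the horizontal axis and of OE against OE_NC on the vertical axis. Circles mark 67 genes with opposite directions and squares 3 with the same direction.

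The 2 negative controls differed more than either pair, with 3215 genes called, 1547 higher and 1668 lower in OE_NC than in si_NC. Cholesterol synthesis and uptake made up the clearest group: 19 of 20 genes were lower in OE_NC, also adjusted over the list alone (median log2 −1.08; limma camera adjusted p = 1.44e-17; adjusted p = 0.679 with an estimated correlation). HMGCS1, which makes HMG-CoA, stood at 42.6 ± 9.41 against 229 ± 65.6 CPM (log2 −2.43 ± 0.27, edgeR adjusted p = 9.02e-05). INSIG1, a sterol-regulated inhibitor of SREBP processing, stood at 5.22 ± 0.507 against 22.3 ± 5.02 CPM (log2 −2.09 ± 0.21, edgeR adjusted p = 3.47e-05). Of 21 genes of fatty acid synthesis and desaturation 11 were lower, or 13 with 1 higher adjusted over the list alone (median log2 −0.47; limma camera adjusted p = 1.24e-05; adjusted p = 0.911 with an estimated correlation). The stearoyl-CoA desaturase SCD stood at 19.0 ± 4.77 against 69.6 ± 19.4 CPM. Of 38 ribosomal protein genes 13 were higher (15 adjusted over the list alone; median log2 0.23; limma camera adjusted p = 0.00205; adjusted p = 0.911 with an estimated correlation). LPIN1, a phosphatidate phosphatase, was lower in OE_NC (log2 −2.00). TRH, also lower (log2 −2.67), shares 363 of its 1544 exon bases with HMGCS1 on the same strand, so its value is uncertain. Higher in OE_NC were PTX3 (11.9 ± 3.94 against 4.01 ± 2.1 CPM), the imprinted RNA H19 (208 ± 39.5 against 81.4 ± 32.7 CPM), MEGF6 (log2 1.56), ENO3 (log2 1.33) and SELENOV (log2 1.29). The labels tell the controls apart only by what was transfected, and give no day or batch. Without OE_NC replicate 2 the count was 1882, and scaling by library totals gave 2298 upward of 3242 genes.

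The median log2 change varied with level, which was not tested. For the 2071 genes at up to 0.5 CPM it was 0.26 for si against si_NC (4 rose, 1 fell), −0.20 for OE against OE_NC (1 rose, 15 fell) and 0.42 for OE_NC against si_NC (98 higher, 15 lower). For the 1709 genes over 100 CPM it was −0.10 (23 rose, 132 fell), 0.073 (158 rose, 53 fell) and −0.12 (123 higher, 490 lower). Genes with at least 1 count numbered 21520 to 23081 in si, 20526 to 20856 in si_NC, 21487 to 21657 in OE and 22541 to 23255 in OE_NC. These numbers depend in part on depth, which was 35.9 to 42.7, 28.9 to 32.2, 32.7 to 36.4 and 35.1 to 38.2 M counts. At similar depth they still differed, as in OE replicate 1 (36.4 M, 21657 genes) and OE_NC replicate 1 (36.0 M, 22694 genes). So did si replicate 1 (36.1 M, 22414 genes) and si replicate 3 (35.9 M, 21520 genes). A pair of libraries also stood apart from their groups: si replicate 3 differed from si replicates 1 and 2 by 20.2 and 21.1 times the Poisson variance of halved counts, where replicates 1 and 2 differed by 2.07. Likewise si_NC replicate 2 differed from replicates 1 and 3 by 21.9 and 13.8, where those differed by 5.26. OE_NC replicate 1 differed from replicates 2 and 3 by 14.1 and 20.4, against 4.07 between those. Both si replicate 3 and si_NC replicate 2 had positive Spearman values of relative level against exon length (0.21 and 0.18), and without both of them 1119 genes changed with si.

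**Figure D5:**
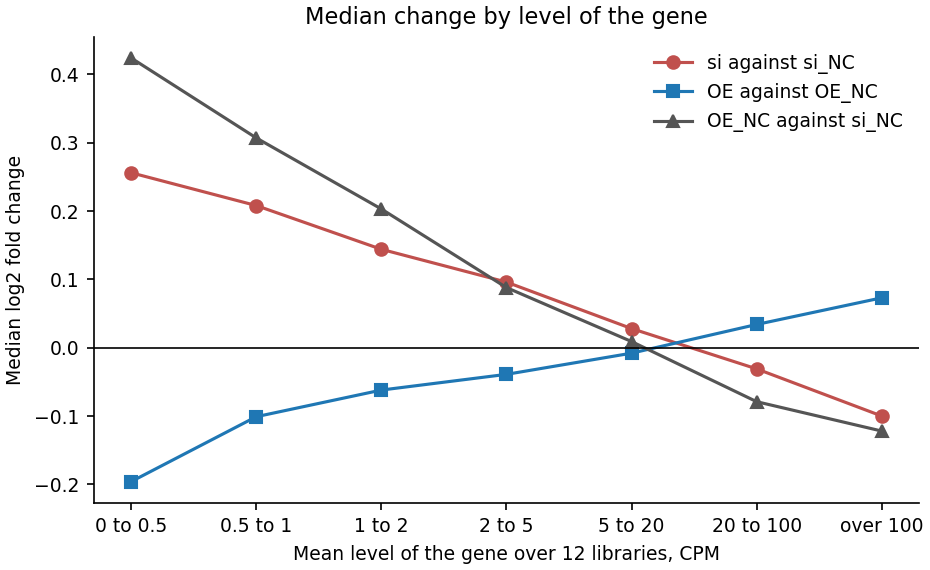
Median log2 fold change of genes grouped by mean level over 12 libraries (CPM, horizontal axis) for si against si_NC, OE against OE_NC and OE_NC against si_NC. From the lowest to the highest group the medians ran from 0.26 to −0.10, −0.20 to 0.073 and 0.42 to −0.12.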

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

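Chosen after the results were seen were the length tests of all 3 patterns below, the tests of immune cells, of single libraries and of plasmid for the interferon genes, and the HGFAC interval; the test of the trend on level and the counts of other splits were set before.

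The response differed between the experiments by a test of the difference itself for 1371 genes, and 67 genes were called in opposite directions, each also called in that test. Opposite calls in the same fit nearly ensure a call of the difference, so this adds no support. In 1 of the 100 joint splits drawn from 200, the real one, as many genes differed. The highest other split still reached 1271, with si replicates 1 and 2 and si_NC replicate 3 set against the rest and the OE groups as they are. Since a regrouping of the si libraries gave nearly as many, the splits do not show that the 2 responses differ beyond chance. For the opposite genes 1 of 100 splits reached 67, the highest other 5. With 1 experiment regrouped, other splits called at most 8 genes for interference and 0 for overexpression. Such splits can hardly hold genes called in both experiments, so they do not test whether the directions are opposite.

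By limma camera with the preset correlation, the list responses that differed (overexpression minus interference, median log2) were mitochondrially encoded proteins (−0.682, adjusted p = 4.23e-12), cholesterol synthesis and uptake (0.353, adjusted p = 0.00284), ribosomal proteins (−0.216, adjusted p = 0.00395), interferon response genes (0.273, adjusted p = 0.00832), immediate early genes (−0.308, adjusted p = 0.0192), p53 targets (0.192, adjusted p = 0.0208) and fatty acid synthesis and desaturation (0.285, adjusted p = 0.0208). With an estimated correlation 0 of these lists passed, with adjusted p-values of 0.557 to 0.915. All 13 mitochondrial genes had a negative difference, 11 of them called; 33 of 44 interferon, 15 of 23 p53, 17 of 20 cholesterol and 17 of 21 fatty acid synthesis genes had a positive one.

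Lower ribosomal transcripts in OE, and less surely the lower mitochondrial ones, may come from the trend on transcript length. With that trend removed from each library, the mean log2 difference OE minus OE_NC of the ribosomal list went from −0.322 ± 0.134 to −0.11 ± 0.075, and that of the mitochondrial list from −0.348 ± 0.052 to −0.144 ± 0.103 (SE over 3 against 3 libraries), each within 2 SE of 0. The mitochondrial SE grew with the correction, which widens that range. Member calls fell to 4 and 1. Across OE_NC replicates 1 to 3 the listed ribosomal share of counts followed the trend (2.6, 2.21 and 2.11 percent). The mitochondrial share did not (1.77, 1.8 and 1.72 percent, against 1.37, 1.33 and 1.31 in OE). It was highest in si replicate 3 (2.26 percent), where the trend was positive. Length is thus a less secure account of the mitochondrial fall. Limma camera at the preset correlation still passed both corrected lists (adjusted p = 0.0429 and 0.0313), though at an estimated one neither passed even uncorrected (0.84 and 0.456), so a part beyond length is not ruled out. For si the mitochondrial list went from 0.293 ± 0.052 to 0.258 ± 0.103, and its called members from 8 to 2. A response to HGFAC stays open, since the length trend and the HGFAC insert differ between the same groups.

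The rise of interferon response genes in OE was not removed by the length trend: their mean log2 difference went from 0.384 ± 0.118 to 0.367 ± 0.114. The 9 immune cell markers tested had a median of −0.204 (mean −0.186, SE 0.123 over genes). Their means were at most 4.4 CPM, too low to exclude a small share of immune cells. A single library is argued against by the lowest median of 6 refits, 0.342 (without OE_NC replicate 1). A response to plasmid or its transcripts cannot be told apart from one to HGFAC, because neither the amount of plasmid nor insert RNA was measured apart from HGFAC; the list differed by a median of −0.011 between OE_NC and si_NC. On the second principal component the OE libraries (21.2 to 24.6) lay with si replicate 3 (24.6) and si_NC replicate 2 (22.3). The other libraries lay at −33.8 to −3.4. A library structure that OE shares with those libraries of the other experiment stays open too. EPSTI1 stood at 51.2 CPM in si replicate 3 (35.7 and 34.01 in replicates 1 and 2). In si_NC replicate 2 it reached 60.4 CPM (37.8 and 34.6 in replicates 1 and 3). OE stood at 50.9 to 55.4 CPM. PARP14 was raised in both libraries too (55.9 and 52.4 CPM, 36.7 to 40.4 elsewhere in si and si_NC). In OE it stood at 62.2 to 64.2 CPM. IRF1 stayed lower in both (9.57 and 10.4 CPM) than in OE (24.97 to 28.9). These genes were picked after seeing values, and the list was neither counted nor tested for this. Whether the rise may follow from HGFAC activity thus stays untested.

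Opposite calls in the 2 experiments were not removed by correction: 75 were called with the length trend removed (9.1 expected) and 58 with the trend on level removed (7.9 expected). Loss of HGFAC mRNA by 2-fold or more in si could not be excluded: its interval ended at −0.919 with all libraries, but at −1.189 without si replicate 1, −1.038 without si_NC replicate 1 and −1.089 without si_NC replicate 2. Shared handling of some libraries stays open, since the labels give no batch. As the labels name no si target, an effect of that target was not tested.

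For the remaining counts of genes, 3 against 3 libraries give 10 splits, too few for a share under 0.05. The real split and the highest other called 414 and 8 genes for interference, 728 and 0 for overexpression and 3215 and 33 for the controls; in each the real split, 1 of 10, was the only one to reach its count. For gene lists in interference 5 of 10 splits called as many as the real 6, up to 13 with si replicates 1 and 3 and si_NC replicate 2 together, which points to a structure of these libraries; in overexpression 2 of 10 reached the real 7, the highest other being 7.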

How the results depend on the processing

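Of the 149 called results for named genes, all 149 kept their sign under every alternative refitted for single genes (the 2-fold minimum was applied to counts only), and 34 were called under every one of those, among them HGFAC, IRF1, BIRC3, INHBA and PFN1 with overexpression, CDH2, SPAG9, FEM1A and CCNG1 with interference, ATP8 in both, and the 10 genes named between the controls. The alternatives reuse the same libraries, and the named results were chosen as called. The largest rises and falls were also required to show no overlap between groups, so a kept sign adds little support. Depth limits HGFAC without the plasmid (10 to 31 reads per library). The fit without si replicate 3 and si_NC replicate 2 together, the length offset and the halved counts were chosen after seeing the data. Except where the construction shows it, the cause was not tested. Leaving out 1 library at a time gave 56 to 1083 changed genes for interference, 19 to 758 for overexpression, 588 to 2152 for the difference, 1882 to 2833 between the controls and 2 to 237 for opposite directions; of the named results a library bears on, leaving out OE replicate 2 ended the calls of 57 of 98 and si_NC replicate 2 those of 4 of 102. The Wald test of DESeq2 gave 1125 (interference), 1546 (overexpression) and 232 (opposite); without the filter on low counts these were 1208, 1679 and 179. A fit of only the groups compared gave 8 and 1621. A change of at least 2-fold, fewer by construction, left 29, 86, 346 (difference), 493 (controls) and 1 (opposite). Without si replicate 3 and si_NC replicate 2 together, 1119 genes changed with interference and 2305 differed; the calls of p53 targets (median −0.015, adjusted p = 0.257), TGF-beta and YAP targets (0.131, 0.085) and epithelial markers (0.774, 0.0775) ended, while DNA replication (−0.169) and fatty acid synthesis (−0.189) passed. The length offset gave 677 and 431. An estimated correlation passed 0 lists in interference and 0 in overexpression (6 and 7 with the preset one), and fry passed 3 in overexpression. Fry did not pass cholesterol and collagens in interference (adjusted p = 0.253 each), nor, in overexpression, interferon genes (adjusted p = 0.058), ribosomal proteins and immediate early genes (0.232 each), collagens and DNA replication (0.293 each); it added anti-adipogenic regulators in interference (0.0182) and, in overexpression, HGF signalling (0.00111), a list that holds HGFAC itself. With the low-count filter dropped, camera added fatty acid synthesis, DNA replication and ribosomal proteins in interference and fatty acid synthesis in overexpression; the 5 CPM filter and limma on RPKM each added G2/M genes in interference and glycolysis in overexpression, and limma on RPKM ended the epithelial call in interference (median 0.138, adjusted p = 0.125). The length offset added ribosomal proteins in interference, and the fit of only the groups compared added fatty acid synthesis in overexpression. The p53 call in interference ended in the fit of only the groups compared (adjusted p = 0.0581) and with the replicate block (0.0517). With replicate number as a block the counts were 17, 76, 305 and, for opposite directions, 1. Residual levels of libraries of the same number correlated at 0.092, −0.257 and −0.191 for si and si_NC. For OE and OE_NC the values were 0.045, −0.01 and −0.015, and si replicate 3 correlated best with si_NC replicate 2 (0.332). So few values cannot settle whether the numbers pair the libraries. The block spends degrees of freedom, but its lower counts remain a limit. Scaling moved the balance of directions. With library totals the median of all genes was 0.104 (interference), −0.061 (overexpression), −0.16 (difference) and 0.112 (controls), against 0.025, −0.005, −0.025 and 0.02 with TMM. Library totals called 298 upward of 404, 159 of 812, 265 of 1534 and 2298 of 3242, against 150 of 414, 362 of 728, 700 of 1371 and 1547 of 3215; limma on log2(RPKM + 1), which keeps those totals, called 245 of 329, 123 of 612, 264 of 1425 and 2288 of 3189 upward, so a split of directions holds only relative to the scaling.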

Other observations

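The test of splicing families on 63 members was set before its result was seen; the values of all 68 members and the genes of the first paragraph were chosen after.

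Stress response genes parted between the negative controls. Of 28 genes of the unfolded protein and integrated stress response, edgeR called 11 higher and 9 lower in OE_NC than in si_NC (13 and 9 adjusted over the list alone), and the list as a whole did not pass limma camera (adjusted p = 0.695). Those higher included ATF4 (306 to 429 CPM, log2 0.49 ± 0.06) and genes known as its targets: the serine synthesis gene PSAT1 (17.9 to 37.4 CPM, log2 1.07 ± 0.21), asparagine synthetase ASNS (log2 0.69 ± 0.14), TRIB3 (log2 1.27 ± 0.23) and CHAC1 (log2 1.31 ± 0.39). Those lower included HSP90B1 (6868 to 4307 CPM, log2 −0.67 ± 0.08), CRELD2 (log2 −1.17 ± 0.21), DNAJC3 (log2 −0.50 ± 0.08) and CALR (log2 −0.30 ± 0.07); HSPA5 was higher (log2 0.20 ± 0.07). Of 17 cytosolic heat shock genes 8 were lower and 1 higher (9 and 3 adjusted over the list alone). HSPH1 (log2 −0.45 ± 0.07) and HSPD1 (log2 −0.40 ± 0.08) were among the lower, and HSP90AA1 was higher (log2 0.28 ± 0.08). Of 25 immediate early genes 7 were higher and 3 lower (8 and 4 adjusted over the list alone), with FOSB (log2 1.97 ± 0.42) and DUSP1 (log2 0.56 ± 0.09) higher and JUND (log2 −0.86 ± 0.16) lower.

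Several genes of RNA splicing were among those that fell with si and rose with overexpression: NSRP1 (log2 −0.35 and 0.32), RBM25 (−0.34 and 0.30), LUC7L3 (−0.38 and 0.32), PRPF38B (−0.30 and 0.28), PRPF4B (−0.35 and 0.24), CWC25 (−0.39 and 0.34) and SYF2 (−0.32 and 0.30). A class response of splicing factor genes was put forward as a hypothesis and tested on 63 other members of 68 genes in families chosen by symbol, 5 having been called in opposite directions. The median log2 change of the 63 was −0.12 with si (limma camera p = 1.6e-08; p = 0.133 with an estimated correlation; 3 fell), and −0.039 with overexpression (limma camera p = 0.495; 1 fell). Though the hypothesis needed a positive median with overexpression, a set that leaves out called genes cannot exclude it. Over all 68 members the medians were −0.16 and −0.025 (29 positive with overexpression), but this set includes the genes that prompted the hypothesis, which cannot support it. Neither set showed the rise with overexpression that the prediction required. By the rule set before the result, the prediction failed for the 63 members. Medians this near 0 do not exclude the hypothesis either, so it stays open.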
